A study of Mus musculus with 10 samples.

How the data were processed

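Cells of 10 mouse hippocampus samples were assayed by droplet single-cell RNA sequencing, with 4 vehicle, 3 FL-NfL and 3 CC-NfL libraries spread over the batches named b1 and b2 in the labels. Per the labels' protocols, both hippocampi of a mouse were dissected after perfusion, dissociated with enzymes in the presence of actinomycin D, stained with a live dye and a dead dye, sorted for live cells and loaded for 3′ library preparation. Actinomycin D blocks transcription and so limits changes of gene expression during dissociation. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.1 against the mouse genome build GRCm38. The filters, the clustering, the rules by which cells were named and the map settings are not given in the sources used here.

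The deposited table lists 108266 barcodes with, for 68914 of them, a condition, a batch, a cluster number, a cell class and map positions. It holds names and positions, no gene values, so the authors' annotation was taken as given and no expression was tested. The remaining 39352 barcodes (36.3%) carry no annotation, for a reason not given in the sources used here, and were left out of the shares. The condition and batch columns matched the labels in all 68914 annotated cells. The annotation holds 32 clusters joined into 16 cell classes, of which 7 hold more than 1 cluster. A second annotation divides the 21630 microglia into 9 subclusters, 5 fine states and 3 coarse states. A further annotation divides 2886 of the 2899 macrophages into 8 fine and 5 coarse states, and 13 macrophages carry no state. The 5 homeostatic subclusters form 1 fine state. The spelling of 1 class name, Pericyte, was corrected.

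The share of a class was its cells as a percentage of the annotated cells of a library. The library was the replicate throughout, never the cell. For the test, the log2 odds, log2((cells + 0.5) / (other cells + 0.5)), were fitted in limma 3.58.1 (R 4.3.3) with group and batch as terms over all 10 libraries, and limma's moderated test was adjusted by the Benjamini-Hochberg method over the items tested. An adjusted p under 0.05 was called a change. Classes, clusters and states with a mean of at least 10 cells per library were tested, which left 16 classes and 31 clusters. The same fit gave 4 contrasts: each protein against vehicle, FL-NfL against CC-NfL, and the mean effect of both proteins against vehicle, named either NfL. Shares of clusters within their class were tested in the same way for 22 clusters, as were 5 microglial states within microglia and 6 macrophage states within macrophages. Limma's moderated test pools the spread over the items of a fit. Shares within a class are not independent, so p-values for states within a class may be too small. Effects are log2 odds ratios with their standard error (SE). All p-values are two-sided except those of the map test and of the permutation tests of composition and cluster make-up. These count only values as large or larger.

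Single percentages were also compared by exact permutation of all splits of the libraries, and within batch. The smallest p this allows is 0.0286 for 4 against 3 libraries and 0.100 for 3 against 3. The composition of a library as a whole was tested by the pseudo-F of Aitchison distances (centred log ratio, 0.5 added), with exact permutation of the groups within batch. Positions on the authors' t-SNE map were compared within each of 12 classes with a mean of at least 50 cells per library. For every cell the 30 nearest neighbours of its class were taken, and the log2 observed over expected share of each other library was averaged over pairs of libraries of the same group minus pairs of different groups, with exact one-sided permutation within batch. Intervals on the share of a single library are exact (Clopper-Pearson, 95%), and a count of 0 was taken to allow up to 3 cells. Both cover counting error alone.

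The contrasts, the tests, the minimum number of cells and most alternatives were fixed before the data were examined, as was the rule for naming: all 16 classes with their values, clusters past the threshold, and the 3 clusters with the largest positive and the 3 with the largest negative estimate per contrast. Classes were grouped by rules fixed at the same time, into resident myeloid cells (microglia), blood-borne immune cells (macrophages), other glia (astrocytes, oligodendrocytes and OPC), the neuronal lineage (neurons, Reelin neurons and NPC), vascular and stromal cells (BMEC, VECA, pericytes, VSMC and VLMC), and ependymal and choroid cells. The annotation does not spell out BMEC, VECA, VSMC, VLMC, OPC or NPC, which were placed by their usual meaning. The class named other immune cells was covered by no rule and stands alone. Macrophages placed among the blood-borne cells can include resident macrophages of the brain borders. States as a share of all annotated cells, all barcodes as the denominator, and fits without the 3 libraries numbered 1 were added after the data had been seen.

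The alternatives were a centred log ratio, the arcsine of the square root of the share, 0.1 or 1 added in place of 0.5, no batch term, the replicate number as a block in place of the batch, only the groups compared, no minimum number of cells, the most abundant class left out, a quasi-binomial logistic model, batch b1 alone and each library left out in turn. The composition test was repeated with Bray-Curtis distance, with clusters, and over all libraries. The map test was repeated with 15 and 100 neighbours, with libraries thinned to equal numbers, and over all libraries. An alternative planned for doublets or cells of low quality was not run, because the annotation names no such class. The centred log ratio was not run for states as shares of all cells, since the states of a class do not make up all cells.

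The test was tried on simulated data, with 100 sets per effect size that had the mean shares, cell numbers and spread of these libraries and 1 item multiplied in the FL-NfL libraries. A 4-fold rise was recovered in 43% of the sets for classes, 15% for clusters, 33% for clusters within a class, 54% for microglial states and 32% for macrophage states. An 8-fold rise was recovered in 66%, 49%, 49%, 95% and 68% of them. A 2-fold rise was recovered in 10% or fewer of the sets at each level. Items left alone were called at 2.87% of tests beside a 4-fold class and at 15.8% beside a 4-fold microglial state, and beside an 8-fold state at 38.2% for microglia and 15.4% for macrophages, since shares of one class sum to a fixed total. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9.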

Results

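Single cells were sequenced from the hippocampi of 10 male wild-type C57BL/6 mice, 11 weeks old, 3 days after injection into both hippocampi. The injections held vehicle (n = 4), full-length neurofilament light chain (FL-NfL, 1 mg/ml, n = 3) or its coiled-coil part (CC-NfL, 1 mg/ml, n = 3). Neurofilament light chain (NfL) is an intermediate filament protein of axons, and the experiment addressed how brain cells respond to NfL supplied from outside. No group received an unrelated protein, so a response to NfL is not separated from a response to any injected protein. Each library held 5434 to 17837 barcodes, of which 3150 to 14141 carried a cell class, and these annotated cells were the depth behind each share. Libraries of batch b1 held 4147 ± 1036 annotated cells (SD, n = 6) and those of batch b2 11008 ± 2334 (SD, n = 4), with an exact permutation p of 0.00476, the smallest that these libraries allow. The share of barcodes without annotation was 51.2% ± 10.8 in b1 and 18.8% ± 1.58 in b2, with the same exact permutation p. Each group had libraries in both batches. Annotated cells numbered 6431 ± 3322 per vehicle library, 6233 ± 4446 per FL-NfL library and 8163 ± 5246 per CC-NfL library, with exact permutation p-values of 0.971 and 0.629 against vehicle. Percentages are means ± SD over 4 vehicle, 3 FL-NfL and 3 CC-NfL libraries, and effects are log2 odds ratios with their SE.

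FL-NfL against vehicle asked which cell classes respond to the whole protein. Macrophages rose from 1.44% ± 0.265 of annotated cells after vehicle to 7.36% ± 2.05 after FL-NfL, 5.11 times the vehicle mean. Other immune cells, a class the annotation divides no further, rose from 0.328% ± 0.0744 to 1.43% ± 0.141, 4.36 times the vehicle mean. Microglia, the resident macrophages of the brain, made up 32.4% ± 5.68 and 31.9% ± 6.70. Both immune classes were higher in 3 of 3 FL-NfL libraries than in any vehicle library, and by chance 3 values lie all above or all below 4 others in 5.71% of splits. The log2 odds ratio was 2.44 (SE 0.46, adjusted p = 0.0103) for macrophages and 2.16 (SE 0.51, adjusted p = 0.0205) for other immune cells, and limma called 2 of 16 classes, as did the quasi-binomial model. In batch b1 macrophages averaged 1.59% after vehicle and 7.52% after FL-NfL, and in b2 1.29% and 7.04%, the latter from 1 library. The macrophage call ended without FL-NfL replicate 3 (adjusted p = 0.0636, log2 odds ratio 2.54) and in batch b1 alone (0.370, 2.27). The call for other immune cells ended without vehicle replicate 1 (0.0586), without vehicle replicate 3 (0.0617), without vehicle replicate 4 (0.0529), without FL-NfL replicate 1 (0.0724), without FL-NfL replicate 2 (0.0603), without FL-NfL replicate 3 (0.0997), with all barcodes as denominator (0.0715) and in batch b1 alone (0.432), with log2 odds ratios of 1.92 to 2.23.

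The remaining classes did not pass the test after FL-NfL. Among other glia, astrocytes made up 5.90% ± 3.17 after vehicle and 4.58% ± 1.40 after FL-NfL, oligodendrocytes 15.6% ± 7.02 and 15.6% ± 7.29, and OPC, the precursors of oligodendrocytes, 16.5% ± 1.87 and 15.2% ± 2.32. In the neuronal lineage, neurons made up 7.18% ± 3.84 and 6.02% ± 1.92, Reelin neurons 0.816% ± 0.542 and 0.464% ± 0.505, and NPC, neural progenitor cells, 6.06% ± 7.14 and 7.23% ± 5.67. Vascular and stromal classes lay at 1.55% ± 0.156 and 1.60% ± 0.378 for BMEC, 0.732% ± 0.566 and 0.399% ± 0.251 for VECA, and 1.25% ± 0.337 and 0.841% ± 0.318 for pericytes. VSMC made up 0.454% ± 0.333 and 0.268% ± 0.269, and VLMC 0.327% ± 0.181 and 0.328% ± 0.305. FL-NfL library 1 held 0 VLMC among 4220 cells, which allows a share of up to 0.0711%. Choroid cells made up 8.49% ± 6.26 and 5.87% ± 4.58, and ependymal cells 0.991% ± 0.414 and 0.891% ± 0.0335. The log2 odds ratios of these classes and of microglia ran from -0.90 (Reelin neurons, SE 1.68) to 0.42 (NPC, SE 1.04). NPC differed more between libraries than between groups, with 16.8%, 13.5% and 20.5% in the libraries numbered 1 of the vehicle, FL-NfL and CC-NfL groups and 1.82% to 5.88% in the other 7.

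**Figure D1:**
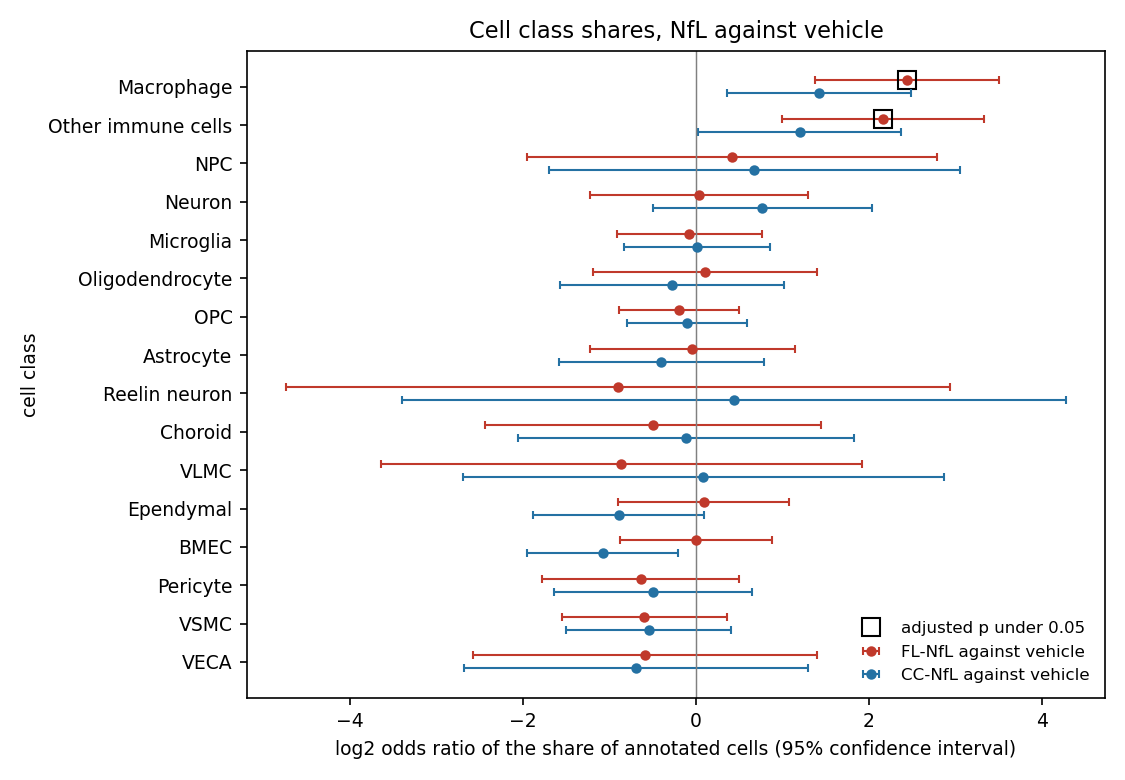
Log2 odds ratio of the share of annotated cells for each of the 16 cell classes, FL-NfL (red) and CC-NfL (blue) against vehicle, with bars for the 95% confidence interval. Squares mark the 2 classes past an adjusted p of 0.05, macrophages (2.44) and other immune cells (2.16), both for FL-NfL.

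CC-NfL against vehicle asked whether the coiled-coil part alone is followed by a response. Macrophages made up 4.05% ± 1.96 of cells after CC-NfL, 2.81 times the vehicle mean and higher in 3 of 3 libraries than in any vehicle library, and did not pass after adjustment (log2 odds ratio 1.43, SE 0.46, adjusted p = 0.174). Other immune cells made up 0.860% ± 0.500 (1.20, SE 0.51, adjusted p = 0.242), higher than every vehicle library in 2 of 3. BMEC, read as brain microvascular endothelial cells, made up 0.803% ± 0.377 against 1.55% ± 0.156 after vehicle, lower in 3 of 3 libraries than in any vehicle library (-1.07, SE 0.38, adjusted p = 0.174). In limma 0 of 16 classes passed, 3 had an unadjusted p under 0.05, and the quasi-binomial model called 0. Without CC-NfL replicate 1, whose macrophages made up 1.94% of cells, both immune classes passed, with adjusted p = 0.0137 for each and log2 odds ratios of 1.88 for macrophages and 1.79 for other immune cells. Over all alternatives the adjusted p of macrophages ran from there to 0.937, in batch b1 only. In batch b1 macrophages averaged 1.59% after vehicle and 3.16% after CC-NfL, and in b2 1.29% and 5.81%, the latter from 1 library.

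Other classes after CC-NfL had log2 odds ratios between -0.89 (ependymal cells, SE 0.43) and 0.77 (neurons, SE 0.55). Microglia made up 29.3% to 36.8% of cells in the 3 libraries (0.02, SE 0.37), astrocytes 3.78% ± 1.65, oligodendrocytes 12.4% ± 4.80 and OPC 16.1% ± 2.95. Neurons made up 9.51% ± 2.35, Reelin neurons 0.701% ± 0.512 and NPC 9.65% ± 9.58. Among vascular and stromal cells, VECA made up 0.346% ± 0.180, pericytes 0.969% ± 0.516, VSMC 0.220% ± 0.117 and VLMC 0.265% ± 0.0107. Choroid cells made up 6.90% ± 3.26 and ependymal cells 0.481% ± 0.212.

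**Figure D2:**
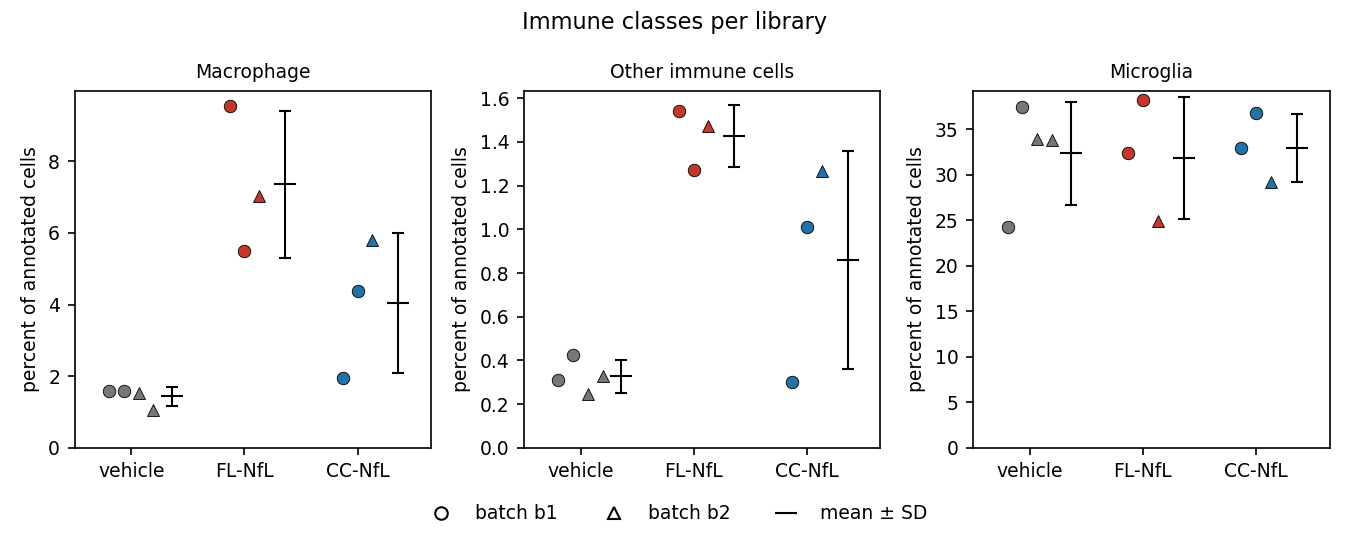
Macrophages, other immune cells and microglia as a percentage of annotated cells, with 1 point per library (circles for batch b1, triangles for b2) and the mean ± SD beside each group. Macrophages made up 5.49% to 9.55% of cells in the 3 FL-NfL libraries, 1.94% to 5.81% in the 3 CC-NfL libraries and 1.05% to 1.60% in the 4 vehicle libraries.

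FL-NfL against CC-NfL asked whether the proteins differ. Macrophages took 7.36% ± 2.05 after FL-NfL and 4.05% ± 1.96 after CC-NfL, a log2 odds ratio of 1.02 (SE 0.49, 95% interval -0.11 to 2.14, adjusted p = 0.378). For other immune cells it was 0.96 (SE 0.54, adjusted p = 0.445) and for BMEC 1.08 (SE 0.40, adjusted p = 0.378). The calls for the immune classes after FL-NfL were therefore not matched by a tested difference from CC-NfL. Limma called 0 of 16 classes, 1 had an unadjusted p under 0.05, and the quasi-binomial model called 0.

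Both NfL groups together were set against vehicle to ask for a response common to the proteins. Macrophages made up 5.70% ± 2.55 of cells over 6 NfL libraries, 3.96 times the vehicle mean, and were higher in 6 of 6 than in any vehicle library (1.93, SE 0.39, adjusted p = 0.0162). Other immune cells were higher in 5 of 6 (1.68, SE 0.43, adjusted p = 0.0341). The exact permutation p for the macrophage percentage was 0.0190 over all splits and 0.0333 within batch, neither of them adjusted over the 16 classes. Limma and the quasi-binomial model each called these 2 of 16 classes. The macrophage call ended without vehicle replicate 3 (adjusted p = 0.0530), without vehicle replicate 4 (0.0640), without FL-NfL replicate 3 (0.0555), without CC-NfL replicate 3 (0.0687) and in batch b1 only (0.828), at log2 odds ratios of 1.58 to 1.99. The call for other immune cells ended without any one library except vehicle replicate 2 (0.0439) and CC-NfL replicate 1 (0.00146), with an adjusted p of up to 0.135 without CC-NfL replicate 3, and also on the arcsine scale, over all barcodes and in batch b1 only.

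Among 31 clusters, cluster 32, which is the whole macrophage class, and cluster 29, which is the whole class of other immune cells, rose after FL-NfL, at the same log2 odds ratios as their classes and with adjusted p-values of 0.0237 and 0.0453. The third largest estimate was cluster 16, a cluster of oligodendrocytes, with 0.901% ± 0.593 of cells after vehicle and 2.09% ± 0.683 after FL-NfL (1.82, SE 0.78, adjusted p = 0.491). The lowest estimates after FL-NfL were those of cluster 19 (Reelin neurons, -0.90, SE 1.70), cluster 22 (VLMC, -0.86, SE 1.23) and cluster 18 (choroid, -0.74, SE 1.06). After CC-NfL limma called 0 clusters, 3 had an unadjusted p under 0.05 and the quasi-binomial model called 0. Its highest estimates were cluster 16 with 2.29% ± 1.46 of cells (1.70, SE 0.78, adjusted p = 0.283), the choroid cluster 12 (1.47, SE 0.74) and cluster 32 (1.43), and its lowest the BMEC cluster 8 (-1.07, SE 0.39), cluster 18 (-0.96) and the ependymal cluster 4 (-0.89, SE 0.44). Between the proteins limma called 0 clusters, 1 had an unadjusted p under 0.05 and the quasi-binomial model called 0. The extremes were clusters 8 (1.08), 32 (1.02) and 4 (0.98), higher after FL-NfL, and cluster 12 (-1.69), cluster 19 (-1.34) and the neuron cluster 3 (-1.16), lower. For both proteins together cluster 32 rose (adjusted p = 0.0368), with cluster 16 at 1.76 (SE 0.66, adjusted p = 0.292) and cluster 29 at 1.68 (adjusted p = 0.0746), and with cluster 18 (-0.85), the VECA cluster 2 (-0.64) and the microglial cluster 30 (-0.60, SE 0.27) lowest. After FL-NfL the call of cluster 32 ended without any 1 of the 7 vehicle and FL-NfL libraries (adjusted p from 0.0550 without FL-NfL replicate 2 to 0.131 without FL-NfL replicate 3), that of cluster 29 without any library but CC-NfL replicate 1 (up to 0.204 without FL-NfL replicate 3), and for both proteins that of cluster 32 without any library but CC-NfL replicate 1 (up to 0.154 without CC-NfL replicate 3). Both calls after FL-NfL also ended over all barcodes, in batch b1 only and without the 3 libraries numbered 1. With the centred log ratio, on the arcsine scale and without the most abundant class, limma called 1 cluster after FL-NfL. The call of cluster 32 for both proteins also ended over all barcodes and in batch b1 only.

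Microglia kept a similar share of cells but shifted between states, most clearly after CC-NfL. The Activated_2 state rose from 10.6% ± 3.92 of microglia after vehicle to 25.6% ± 5.34 after CC-NfL, 2.41 times the vehicle mean, and the homeostatic state fell from 74.1% ± 8.68 to 51.4% ± 7.45. After FL-NfL, Activated_2 made up 20.2% ± 3.59 and homeostatic microglia 61.0% ± 9.50. Activated_2 was higher in 6 of 6 NfL libraries than in any vehicle library. For CC-NfL the log2 odds ratio was 1.63 for Activated_2 (SE 0.52, adjusted p = 0.0209) and -1.49 for the homeostatic state (SE 0.53, adjusted p = 0.0240), each beyond all vehicle libraries in 3 of 3. For FL-NfL they were 1.19 (adjusted p = 0.151) and -0.91 (adjusted p = 0.252), and limma called 0 of 5 states, with 1 at an unadjusted p under 0.05 and 0 by the quasi-binomial model. Limma's p-values for states rest on a spread pooled over the 5 states, which are not independent. The calls of microglial states may therefore rest on p-values that are too small. FL-NfL and CC-NfL differed by -0.44 (SE 0.55) for Activated_2 and 0.59 (SE 0.56) for the homeostatic state, each with an adjusted p of 0.707. Limma called 0 states between the proteins, 0 had an unadjusted p under 0.05 and the quasi-binomial model called 0. For both proteins together, Activated_2 rose (1.41, SE 0.44, adjusted p = 0.0182) and the homeostatic state fell (-1.20, SE 0.45, adjusted p = 0.0340), lower than every vehicle library in 5 of 6, while FL-NfL library 3 at 72.0% lay within the vehicle range of 68.5% to 86.9%. The quasi-binomial model called 0 of 5 for this contrast, with an adjusted p of 0.0526 for Activated_2 and 0.116 for the homeostatic state.

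The microglial percentages were also compared by exact permutation, which gave p = 0.00476 over all splits and 0.0111 within batch for Activated_2 in NfL against vehicle libraries (0.0238 after adjustment over all splits). The homeostatic state had an exact permutation p of 0.0333 over all splits, 0.0833 after adjustment, so its call in limma was not matched there, and Activated_2 after FL-NfL had 0.0286, 0.143 after adjustment. In batch b1 Activated_2 averaged 8.33% after vehicle, 22.2% after FL-NfL and 27.2% after CC-NfL, and in b2 12.9%, 16.1% and 22.5%. Homeostatic microglia averaged 77.9%, 55.5% and 49.1% in b1 and 70.3%, 72.0% and 55.8% in b2. Activated_1 made up 6.95% ± 1.40, 9.49% ± 3.44 and 10.9% ± 2.49 of microglia after vehicle, FL-NfL and CC-NfL. Activated_3 made up 3.75% ± 2.34, 5.10% ± 2.17 and 5.11% ± 1.12, and proliferating microglia 4.56% ± 1.42, 4.21% ± 1.79 and 6.97% ± 1.21. None of these 3 states passed in limma in any contrast with all libraries, though Activated_1 was higher in 3 of 3 CC-NfL libraries than in any vehicle library (exact permutation p = 0.0286, 0.0476 after adjustment), and in limma Activated_3 passed without vehicle replicate 2 (adjusted p = 0.0228 for CC-NfL and 0.0164 for both proteins). Shares of microglia sum to a fixed total, and as shares of all cells limma called 0 states after CC-NfL and 0 for both proteins, in each case with 2 at an unadjusted p under 0.05 and 1 by the quasi-binomial model. Both calls for CC-NfL ended without CC-NfL replicate 1 (adjusted p = 0.0534 for each), without CC-NfL replicate 2 (0.154 for each) and without CC-NfL replicate 3 (0.0722 for Activated_2 and 0.0787 for the homeostatic state), and the homeostatic call also with the centred log ratio (0.0691). For both proteins the Activated_2 call ended without vehicle replicate 3 (0.0524), without FL-NfL replicate 1 (0.0640), without FL-NfL replicate 2 (0.0554) and without CC-NfL replicate 2 (0.0774), and the homeostatic call without any library except vehicle replicate 2, vehicle replicate 4 and FL-NfL replicate 3 (up to 0.102, without CC-NfL replicate 2). Without vehicle replicate 1, which held the most homeostatic cells, the homeostatic log2 odds ratio for both proteins was -0.67 (adjusted p = 0.0650) and that of Activated_2 0.94 (adjusted p = 0.0138). With the centred log ratio 1 state was called for each protein against vehicle and 1 for both together. Fits without the 3 libraries numbered 1 called 1 state between the proteins and 1 for both together.

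**Figure D3:**
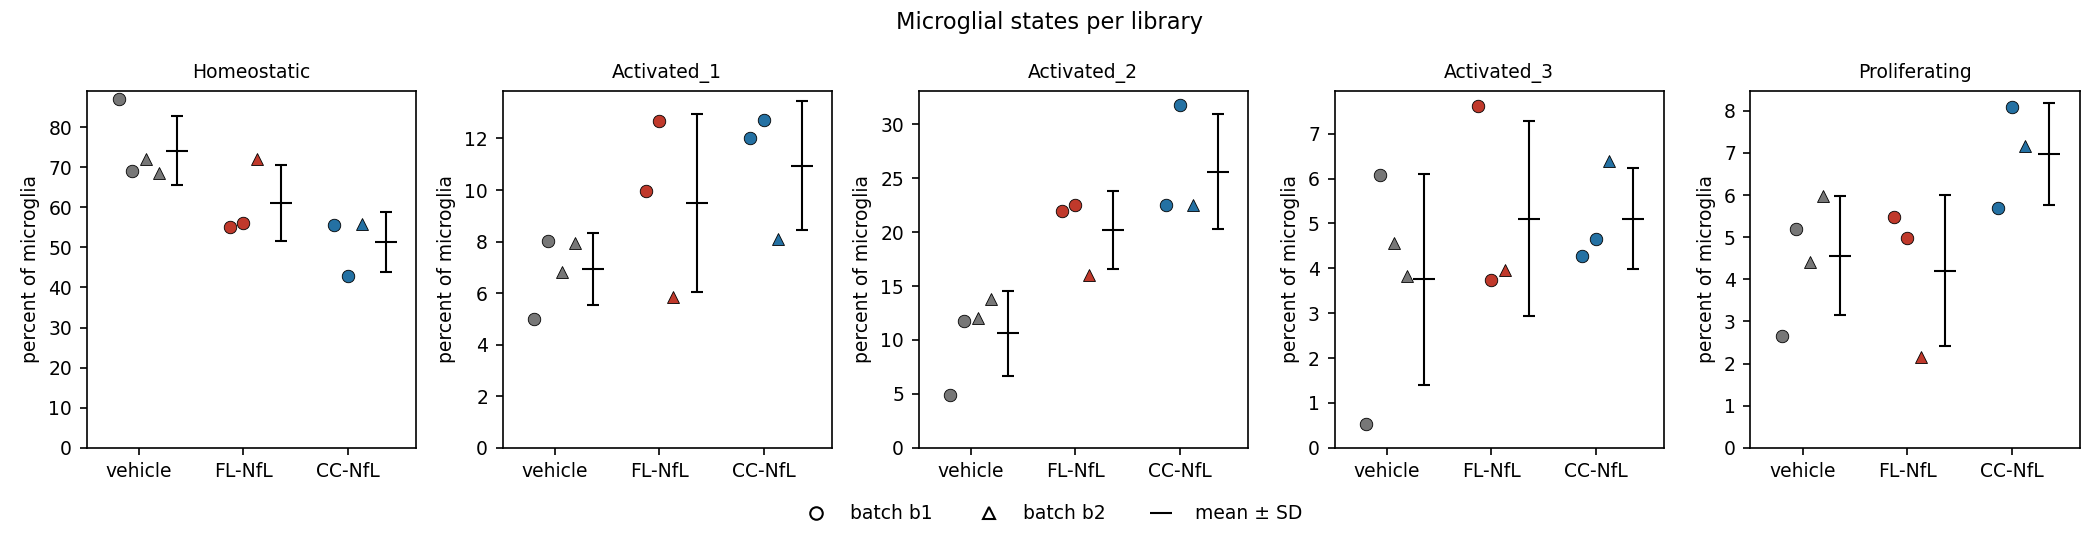
Microglial states as a percentage of the microglia of each library, with 1 point per library (circles for batch b1, triangles for b2) and the mean ± SD beside each group. Activated_2 made up 16.1% to 31.8% of microglia in the 6 NfL libraries and 4.90% to 13.8% in the 4 vehicle libraries.

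The make-up of macrophages by state differed from vehicle after each protein, with estimates of the same sign for both as shares of macrophages. Both contrasts use the same vehicle libraries, so their estimates are not independent. The 3 activated states together made up 12.2% ± 7.33 of macrophages after vehicle, 58.1% ± 16.2 after FL-NfL and 59.8% ± 17.8 after CC-NfL. MHC2_low macrophages fell from 37.5% ± 9.16 to 11.6% ± 4.00 and 14.9% ± 8.28, lower in 6 of 6 NfL libraries than in any vehicle library. MHC class II molecules, to which these names refer, present antigen to helper T cells. Activated_1 rose from 4.04% ± 5.18 to 17.6% ± 6.54 and 21.6% ± 13.3, Activated_2 from 1.80% ± 2.09 to 16.4% ± 7.83 and 18.5% ± 7.90, and Activated_3 from 6.37% ± 1.80 to 24.2% ± 4.23 and 19.6% ± 3.01. Each of the 3 activated states was higher in 6 of 6 NfL libraries than in any vehicle library. The log2 odds ratios for FL-NfL and CC-NfL were 2.92 and 3.21 for Activated_1 (SE 0.95, adjusted p = 0.0216 and 0.0136), 3.48 and 3.75 for Activated_2 (SE 0.90, adjusted p = 0.00900 and 0.00584), 2.06 and 1.68 for Activated_3 (SE 0.33, adjusted p = 0.00122 and 0.00266) and -2.40 and -2.14 for MHC2_low (SE 0.42, adjusted p = 0.00122 and 0.00266). MHC2_high_1 made up 36.6% ± 17.3, 15.5% ± 12.4 and 10.2% ± 6.44, a fall that passed after CC-NfL (-2.53, SE 0.96, adjusted p = 0.0350) and not after FL-NfL (-1.99, adjusted p = 0.0706). MHC2_high_2 made up 4.92% ± 2.60, 12.2% ± 1.66 and 11.3% ± 5.15, a rise that passed after FL-NfL (1.42, SE 0.54, adjusted p = 0.0347) and not after CC-NfL (1.24, SE 0.54, with an adjusted p just over the threshold).

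Limma and the quasi-binomial model each called 5 of 6 macrophage states for each protein against vehicle. Between FL-NfL and CC-NfL limma called 0 states, with 0 at an unadjusted p under 0.05 and 1 by the quasi-binomial model (Activated_3, 0.57, adjusted p = 0.0392), at an adjusted p of 0.782 for each of the 6 states in limma and estimates from -0.29 (Activated_1) to 0.54 (MHC2_high_1). For both proteins together limma called 6 of 6, with log2 odds ratios from -2.27 (MHC2_low) to 3.62 (Activated_2). Vehicle libraries held 52 to 150 macrophages each, which limits the precision of their shares, and in simulated data 15.4% of tests of unchanged macrophage states gave a call beside a state raised 8-fold. Only 1 state was raised in those data, while 3 activated states rose here, so that rate does not cover this case. Falls within macrophages may come from the fixed total more often. Granulocytes (56 cells) and proliferating macrophages (35 cells) were too few to test. For FL-NfL, the Activated_1 call ended without vehicle replicate 1 (adjusted p = 0.0691), without FL-NfL replicate 1 (0.0606), without FL-NfL replicate 2 (0.0502) and without FL-NfL replicate 3 (0.0981), the Activated_2 call without FL-NfL replicate 3 (0.0626), and the MHC2_high_2 call without vehicle replicate 1 (0.0985), without vehicle replicate 4 (0.0677) and without any FL-NfL library (up to 0.123), while MHC2_high_1 passed without vehicle replicate 2 (0.000557). For CC-NfL, the Activated_1 call ended without CC-NfL replicate 3 (0.0861) and the MHC2_high_1 call without vehicle replicates 1, 3 and 4, without FL-NfL replicate 1 and without CC-NfL replicates 2 and 3 (0.0532 to 0.165), while MHC2_high_2 passed without vehicle replicate 2 (0.00804) and without CC-NfL replicate 1 (0.0452). For both proteins, the MHC2_high_1 call ended without vehicle replicates 1, 3 and 4 and without FL-NfL or CC-NfL replicate 3 (0.0584 to 0.0821), and the MHC2_high_2 call without vehicle replicates 1 and 4 and without FL-NfL replicate 3 (0.0521 to 0.0752). The calls for Activated_3 and MHC2_low held without each library in turn, and in batch b1 alone they ended for each protein (0.0647 to 0.0990) and held for both together (0.0445). No macrophage state was called for FL-NfL or for CC-NfL in batch b1 alone. Without the 3 libraries numbered 1, limma called 2 states for each protein and 2 for both together. With only the groups compared it called 3 for CC-NfL.

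Shares within a class move together, so the macrophage states were also taken as shares of all annotated cells, a comparison added after the data had been seen. Activated_1 rose from 0.0592% ± 0.0833 to 1.30% ± 0.562 after FL-NfL and 1.02% ± 0.986 after CC-NfL, with 0.182% in vehicle library 2 and up to 0.0341% in the other vehicle libraries. Activated_2 rose from 0.0280% ± 0.0326, a total of 7 cells in the vehicle libraries, to 1.26% ± 0.744 and 0.792% ± 0.658, and vehicle libraries 1 and 4 held 0 such cells, which allows shares of up to 0.0774% and 0.0341%. Activated_3 rose from 0.0945% ± 0.0387 to 1.82% ± 0.809 and 0.755% ± 0.278, and MHC2_high_2 from 0.0713% ± 0.0436 to 0.878% ± 0.183 and 0.481% ± 0.311. MHC2_low made up 0.550% ± 0.202, 0.810% ± 0.168 and 0.507% ± 0.241 of all cells, and MHC2_high_1 0.520% ± 0.272, 1.04% ± 0.660 and 0.330% ± 0.115, and neither passed. Limma called 4 of 6 states for each protein, the rises above, with log2 odds ratios from 2.53 (MHC2_high_2, CC-NfL, SE 0.69) to 5.59 (Activated_2, FL-NfL, SE 1.03) and adjusted p-values from 0.000239 to 0.00758. Each of these states was higher in 3 of 3 FL-NfL and 3 of 3 CC-NfL libraries than in any vehicle library. The contrast of FL-NfL with CC-NfL called 0 states in limma, with 0 at an unadjusted p under 0.05 and 0 by the quasi-binomial model.

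**Figure D4:**
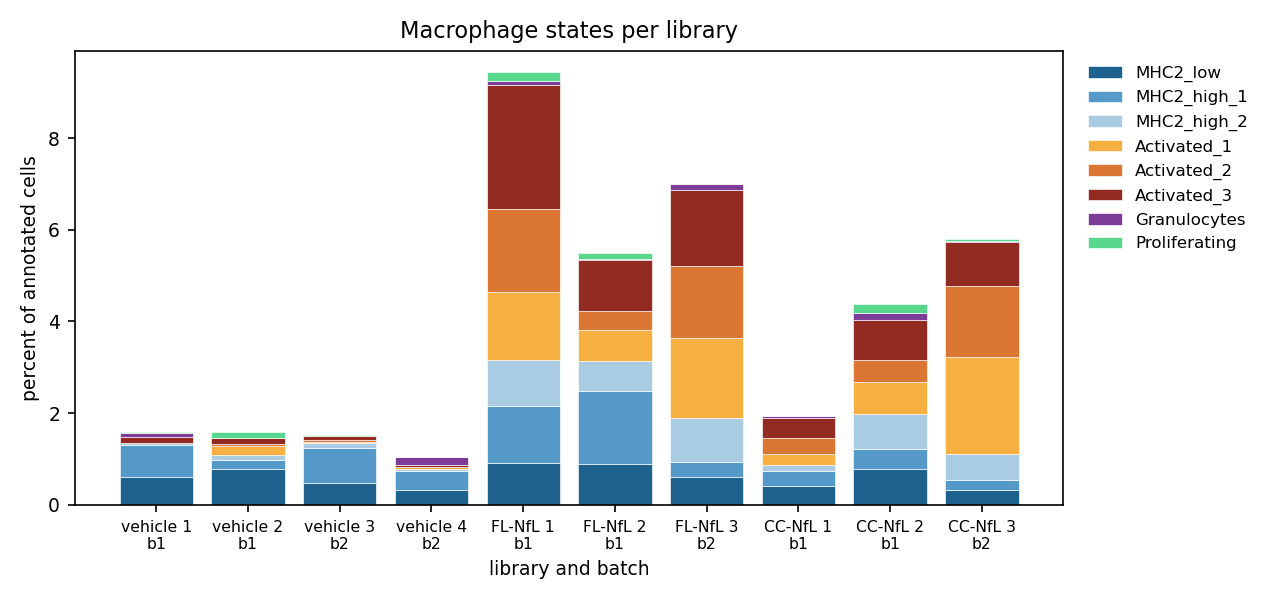
Macrophage states as a percentage of the annotated cells of each library, stacked from 0, with the library and its batch on the horizontal axis. Activated states (yellow to red) made up little of the 4 vehicle libraries, where Activated_2 averaged 0.0280% of cells, against 1.26% after FL-NfL and 0.792% after CC-NfL.

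Clusters were also compared as shares of their class, which separates the make-up of a class from its size. OPC of cluster 15 made up 18.6% ± 3.22 of OPC in vehicle libraries and 30.7% ± 3.22 in the 6 NfL libraries, higher in 6 of 6, and OPC of cluster 6 77.5% ± 3.56 and 66.1% ± 2.99. Microglia of cluster 21 made up 15.2% ± 6.52 and 32.2% ± 7.08 of microglia, and those of cluster 30 54.2% ± 8.70 and 39.7% ± 6.37. Astrocytes of cluster 26 made up 10.8% ± 2.04 and 20.9% ± 7.97 of astrocytes, oligodendrocytes of cluster 16 7.29% ± 7.66 and 15.7% ± 5.60 of oligodendrocytes, and neurons of cluster 17 69.3% and 53.8% of neurons. These values were picked after they had been seen, and none passed the adjustment over 22 clusters. For both proteins the log2 odds ratio of OPC cluster 15 was 0.98 (SE 0.26, adjusted p = 0.0852) and that of microglial cluster 30 was -0.95 (SE 0.28, adjusted p = 0.0852). Limma called 0 clusters for both proteins, with 8 at an unadjusted p under 0.05 and 3 by the quasi-binomial model. After CC-NfL it called 0, with 8 at an unadjusted p under 0.05 and 6 by the quasi-binomial model. In both contrasts the 8 held both clusters of astrocytes, whose shares mirror each other, and OPC clusters 6 and 15, which moved in opposite directions. They are therefore not 8 separate changes. The counts after FL-NfL were 0 in limma, 2 at an unadjusted p under 0.05 and 0 by the quasi-binomial model, and those between the proteins were 0, 0 and 0.

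Taken over all 16 classes at once, composition was not shown to differ between groups. The groups accounted for 22.9% of the squared Aitchison distances between libraries (pseudo-F 1.04, exact permutation p = 0.450 over 1080 permutations within batch). Pairs of groups gave exact permutation p-values of 0.444 for FL-NfL and 0.500 for CC-NfL against vehicle, where the smallest possible was 0.0556, and 0.667 between the proteins, where it was 0.167.

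Cells of some classes lay nearer to cells of libraries of their own group on the authors' map. With the 3 groups kept apart, 6 of 12 classes passed: macrophages, microglia and OPC (adjusted p = 0.00741 each, from an exact permutation p of 0.00185, the smallest that the design allows), ependymal cells (0.0111), choroid cells (0.0296) and oligodendrocytes (0.0296). The log2 excess of neighbours of the same group over the mean of the permutations was 0.60 for macrophages, 0.23 for microglia, 0.14 for OPC, 0.22 for ependymal cells, 0.24 for choroid cells and 0.11 for oligodendrocytes. With vehicle set against both NfL groups together, choroid cells, ependymal cells and OPC passed (adjusted p = 0.0444 each, from the smallest possible exact p of 0.0111). On their own maps, microglia and macrophages each gave an exact permutation p of 0.00741 for the 3 groups. The number for 3 groups fell to 0 without vehicle replicate 1, without vehicle replicate 2, without CC-NfL replicate 1 and without CC-NfL replicate 2, to 3 without vehicle replicate 3, vehicle replicate 4 or FL-NfL replicate 3, and to 1 when permuted over all libraries. That for vehicle against NfL fell to 0 when permuted over all libraries. It was also 0 without any 1 library, but fewer permutations then remained and 3 classes at the smallest possible p could not have passed. Those fits therefore cannot show whether the result depends on a library.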

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

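Every test of an explanation given here was chosen after the result it concerns had been seen. In the vehicle group, 29 sets of 4 values (classes, states and totals) were searched for a library far from the other 3, and 3 were found, where chance gives about 1 in 20. Macrophages made up 1.05% of cells in vehicle library 4 (exact 95% interval 0.844% to 1.28%) against 1.54% to 1.60% in the other 3. NPC made up 16.8% in vehicle library 1 (15.6% to 18.0%) against 1.82% to 2.98%. Reelin neurons made up 0.0114% in vehicle library 4, 1 cell of 8800 (0.000288% to 0.0633%), against 0.973% to 1.16%. Barcodes without annotation, which carry no cell class, made up 71.3% of FL-NfL library 1 and 53.0% of CC-NfL library 1, above the 48.7% to 50.3% of the vehicle libraries of the same batch, while FL-NfL library 2 at 42.0% and CC-NfL library 2 at 42.1% lay below them.

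Macrophages took a larger share of cells in the NfL libraries. Uneven loss of unannotated barcodes is argued against by batch b2 as far as their number goes. There 17.3% to 20.7% of barcodes were left out in every library and the NfL mean was still 4.98 times the vehicle mean. The lowest interval of an NfL library (from 5.43%) lay above the highest of a vehicle library (to 1.80%), though these intervals cover counting error alone. Which kinds of cell were left out is not given, so an uneven loss by cell class stays open. Fewer cells of all other classes cannot be told apart from more macrophages, since both give the same shares and the same centred log ratio, which was 1.84 higher (SE 0.42, adjusted p = 0.0224). Blood carried over into the suspension also remains open, since granulocytes, a blood cell, had a log2 odds ratio of 0.63 (95% interval -1.22 to 2.47, 56 cells, 21 of them in vehicle libraries), which overlaps that of macrophages. Entry or growth of macrophages after NfL, or after any injected protein, is the untested biological explanation.

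Activated_2 made up more of the microglia in all NfL libraries than in any vehicle library, and the homeostatic state less in 5 of 6. For both proteins together, a difference between batches is argued against by exact permutation within batch, with p = 0.0111 for Activated_2 and 0.0222 for the homeostatic state. For FL-NfL alone no state passed in limma. Its homeostatic mean was 55.5% against 77.9% after vehicle in b1, but 72.0%, from 1 library, against 70.3% in b2. A single vehicle library with few activated cells is argued against as the only source of the rise of Activated_2. Its log2 odds ratio was 0.94 without vehicle replicate 1 (SE 0.28, adjusted p = 0.0138 in limma). With all libraries it was 1.41 (SE 0.44), so that library did raise the estimate. Whether both states moved, or 1 moved and the fixed total of shares moved the other, cannot be told apart, because as shares of all cells the estimates were 1.24 (SE 0.49) and -0.51 (SE 0.19) with an adjusted p of 0.0928 for each (unadjusted 0.0371 and 0.0253), and other tests of these shares went apart: adjusted p was 0.00653 and 0.0166 on the arcsine scale, 0.206 and 0.00416 in the quasi-binomial model and 0.0833 and 0.0476 by exact permutation. A change of state in response to the injected protein stays open beside it.

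NPC took a larger share in the libraries numbered 1 of all 3 groups, which no group of the design explains, and no biological explanation was tested. If libraries of 1 number had been handled together, other classes might differ from number 1 to number 2 in the same way in each group, but over 15 other classes the correlations between groups ran from -0.461 to 0.188, which leaves this open. More tissue lining the ventricle also stays open. The summed share of choroid and ependymal cells was highest in number 1 in 1 of the 3 groups, but that sum is mostly choroid cells. Ependymal cells alone were highest in number 1 among the FL-NfL libraries and lowest in number 1 among the CC-NfL libraries. In the vehicle group number 1 lay between the others.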

How the results depend on the processing

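The added alternatives (all barcodes, no libraries numbered 1, states as shares of all cells) were chosen after the data had been seen. Of 708 alternative values of counts and overall tests, 594 kept their value within the limits set and 114 moved; of 2879 alternative values of single classes, clusters and states, 2704 stayed on their side of the threshold, 22 gained a call and 0 changed direction, and of the 840 that concern a result called with all libraries 687 kept the call and 153 lost it. Counts are given in the order FL-NfL, CC-NfL, FL-NfL against CC-NfL and either NfL where several are named, and the cause of a change was not tested unless stated. Classes passed 1 time for FL-NfL and 1 time for either NfL over all barcodes, 0 times for both in batch b1 only, 2 for CC-NfL without the 3 libraries numbered 1, and for either NfL 1 on the arcsine scale and 0 with the replicate block. That block takes libraries of 1 number as matched, which the labels do not say. Deviations of such libraries from their group means correlated from -0.128 to 0.539 across classes, with 4 of 9 libraries closest to their own number, and from 0.0748 to 0.672 across clusters, with 8 of 9 closest. Batches hold different numbers, and from group and batch means the values were -0.308 to 0.544 and 2 of 9 across classes and -0.220 to 0.675 and 5 of 9 across clusters. With the replicate block in place of the batch the adjusted p for either NfL was 0.0852 for macrophages and for other immune cells. Clusters for FL-NfL numbered 1 with the centred log ratio, 1 on the arcsine scale, 0 with the replicate block, 1 without the most abundant class, 0 over all barcodes, 0 in batch b1 only and 0 without the 3 libraries numbered 1; for either NfL they numbered 0 with the replicate block, 0 over all barcodes, 4 in the quasi-binomial model, 0 in batch b1 only and 2 without the 3 libraries numbered 1. Clusters within a class numbered 6 for CC-NfL in the quasi-binomial model, and for either NfL 3 on the arcsine scale, 3 with the replicate block and 3 in the quasi-binomial model. Microglial states numbered 1 with the centred log ratio for FL-NfL, for CC-NfL and for either NfL; without the 3 libraries numbered 1 they numbered 1 between the proteins and 1 for either NfL, and 0 for either NfL in the quasi-binomial model. Macrophage states numbered 0 for FL-NfL, 0 for CC-NfL and 3 for either NfL in batch b1 only, 2 for each of these without the 3 libraries numbered 1, 3 for CC-NfL with only the groups compared, and 1 between the proteins in the quasi-binomial model. Batch b1 holds 2 libraries per group, so fewer samples lie behind its counts. As shares of all cells, macrophage states numbered 1 for CC-NfL in batch b1 only, and microglial states 1 for FL-NfL, 1 for CC-NfL and 1 for either NfL in the quasi-binomial model and 2 for CC-NfL and 2 for either NfL on the arcsine scale. Leaving out 1 library at a time gave 0 to 2 classes for FL-NfL, 0 to 2 for CC-NfL and 0 to 2 for either NfL, and 0 to 2 clusters for each of the same contrasts. It gave 0 to 3 microglial states for CC-NfL and 0 to 3 for either NfL (0 to 1 for both as shares of all cells), and 2 to 6 macrophage states for FL-NfL and 3 to 6 for CC-NfL. On the map it gave 0 to 6 classes for 3 groups and 0 to 0 for vehicle against NfL; permuted over all libraries these were 1 and 0, with 15 neighbours 4 and 3, with 100 neighbours 4 and 3, and thinned to the smallest library 5 and 4 of the 10 classes left. Fewer permutations remain when a library is left out, so the smallest p is larger. Depth limits the macrophage states, with 52 macrophages in the smallest library. Not run were doublets left out, as no class is named so, and the centred log ratio of states as shares of all cells.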

Other observations

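All tests of explanations in this part, and the counts of other splits of the libraries, were chosen after the results had been seen. Within the homeostatic microglia, the decline lay most in subcluster 1, which made up 20.3% ± 3.44 of microglia after vehicle and 10.5% ± 3.66 after CC-NfL (-1.18, SE 0.34, adjusted p = 0.0202). That call ended without CC-NfL replicate 2 (0.0570) and without CC-NfL replicate 3 (0.0937). The other 4 homeostatic subclusters had estimates from -0.76 to -0.20 and did not pass. Activated microglia as a whole made up 21.3% ± 7.33 after vehicle, 34.8% ± 7.72 after FL-NfL and 41.7% ± 6.56 after CC-NfL, with adjusted p-values of 0.126 and 0.0128. Limma pooled the spread of this test over coarse states that are not independent, so these p-values may be too small. Granulocytes made up 6.13% ± 8.05 of macrophages after vehicle, 1.20% ± 0.739 after FL-NfL and 2.05% ± 1.55 after CC-NfL, where vehicle library 4 held 17.4% and the other vehicle libraries up to 6.45%.

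Cluster make-up within a class was tested in 7 classes for a shift with treatment, by permutation of vehicle and NfL labels within batch. OPC gave an exact p of 0.0111, the smallest that 90 permutations allow (adjusted 0.0778), microglia 0.0222 (0.0778), astrocytes 0.0444 (0.104), oligodendrocytes 0.0667 (0.117), choroid cells 0.144 (0.202) and NPC 0.333 (0.389), and neurons 0.689 (0.689). None passed after adjustment over 7 classes, where a single class at the smallest p could not have passed, so a shift stays open for all 7.

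FL-NfL and CC-NfL effects went together over 31 clusters, with a correlation of 0.69 across clusters and the same sign in 22. The shared vehicle libraries may account for this, since simulated data with no effect gave correlations up to 0.802 at the 95th percentile, and with the vehicle libraries split between the proteins the correlation ran from -0.02 to 0.25. Clusters are not independent replicates. A barcode sequence seen in more than 1 library carried the same class in both in 15.7% of cases (exact 95% interval 12.8% to 19.1%), against 16.7% for random cells of the same libraries, which argues against the same cells having been read in both.

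Other splits of the libraries were fitted as the groups had been, to ask whether chance could give as many calls. The bound was under 5% of splits, not adjusted for the number of counts, and for either NfL the 100 splits were drawn at random from all regroupings of the 10 libraries. For either NfL against vehicle, counts under the bound were those of classes (2 called, as many in 3 of 100 splits, highest other 2), clusters (1, in 4 of 100, highest other 2), microglial states (2, in 2 of 100, highest other 4) and macrophage states (6, in 1 of 100, highest other 3). The real split is counted among the 100, and other splits gave as many calls or more for classes, clusters and microglial states. A sample of this size therefore does not exclude chance for those, while for macrophage states no other sampled split gave as many. For FL-NfL against vehicle, clusters fell under the bound (2, in 1 of 35, highest other 0). Their 2 calls are the whole macrophage class and the whole class of other immune cells. As classes these did not fall under the bound, so chance is not excluded for them. The bound was not met, and chance not excluded, for the classes after FL-NfL (2, in 2 of 35, highest other 2), the microglial states after CC-NfL (2, in 3 of 35, highest other 3), the macrophage states after FL-NfL (5, in 2 of 35, highest other 6) and after CC-NfL (5, in 2 of 35, highest other 6). In both of the latter the other split set vehicle libraries 1, 3 and 4 against the rest, so it differed from the real one by vehicle library 2, which held few MHC2_high_1 and more Activated_1 cells than the other vehicle libraries. That split kept all NfL libraries of the contrast on the same side, so it carried the treatment difference and was no draw without it. With 35 splits 1 such split is enough to miss the bound, so these counts of macrophage states cannot decide about chance. The highest other for microglial states after CC-NfL was the same split. As shares of all cells, macrophage states gave 4 after FL-NfL (in 2 of 35, highest other 4), 4 after CC-NfL (in 2 of 35, highest other 5) and 4 for either NfL (in 7 of 100, highest other 4), and chance was not excluded for any of them. After each protein the other split was again that of vehicle libraries 1, 3 and 4, so those counts cannot decide either.

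Where the real count was 0, every split was as large. That held for classes and clusters after CC-NfL (35 of 35, highest others 2 and 1), for clusters within a class after FL-NfL, CC-NfL and either NfL (35 of 35, 35 of 35 and 100 of 100, highest others 1, 2 and 3), for microglial states after FL-NfL (35 of 35, highest other 3) and for microglial states as shares of all cells (35 of 35, 35 of 35 and 100 of 100, highest others 4, 0 and 1). The split with 3 microglial states set vehicle library 2 and FL-NfL libraries 1 and 2 against the rest, which placed FL-NfL library 3 with the vehicle libraries. FL-NfL against CC-NfL allows 10 splits, too few for a share under 0.05, and gave 0 calls at every level, with 0 to 1 in the highest other.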
